A study of Mus musculus with 2 samples.

How the data were processed

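Total RNA was extracted from the epidermis of 5-day-old mice with a keratinocyte deletion of Casr and of littermate controls with floxed Casr alleles. Per the labels' protocols, back skin was treated with dispase to lift the epidermis from the dermis, RNA was extracted from each mouse, cleaned and treated with DNase, and RNA from 3 mice was combined for each group. The RNA was labelled with biotin and detected with Cy3-streptavidin on Illumina bead arrays, 1 array for each group. GenomeStudio 2011.1 is named in the submitters' processing notes. Both arrays lay on the same chip per the file headers. One sentence of the labels' protocols names a vitamin D receptor knockout group, while all other labels of both samples name the CaSR knockout, and the latter were followed. The series' design text gives 3 animals for each group, and the files hold 1 column of signals for each group, so each group counted as 1 sample.

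The deposited tables give 1 linear intensity and 1 detection p-value for each of 25697 probes and each sample. Per the file headers, the authors deposited a table of intensity before normalization and a table after it. The normalization method is not given in the sources used here. In the values, the ranked intensities of the 2 arrays matched to within 1 percent at all probes after normalization (both medians were 148.9), whereas the medians before normalization were 161.3 in the control sample and 166.1 in the knockout sample. The lowest normalized intensity was 106.2 in both, so the background had not been subtracted, which draws ratios of weak signals towards 1. The authors' value table for the series was identical to the normalized table (maximum difference 0). The detection p-value deposited by the authors moves in steps that a rank among 798 negative control beads would give.

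Normalized intensities were raised to a floor, the lowest signal among probes with a detection p-value of at most 0.01 in that array (164.9 in the control and 165.9 in the knockout sample), and log2 transformed. A gene was included if a probe had a detection p-value of at most 0.01 in at least 1 sample, and its probe with the highest mean signal represented it. Folds and log2 ratios are knockout over control. Where a gene was detected in 1 sample, the ratio against the floor or the dim signal, whichever was higher, is a bound, written as at least N-fold. Probe annotation was updated through the gene ID and then the accession against RefSeq genes of the mouse assembly GRCm38.p6, used for names and neighbour order only. Of the probes, 24358 matched a current symbol and 1339 kept the symbol in the file. Genes with predicted or clone names (356) were counted and not named.

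With 1 sample in each group no significance test was made, and the counts of genes at least 1.5-fold apart are descriptions of these samples. Precision within an array was described by the spread of log2 ratios between different probes of a gene. Each gene list was described by the median log2 ratio of its detected members and by the percentile of that median among 10000 random lists of the same size, matched on mean signal in 10 bins, and a list was said to stand apart outside the percentiles 2.5 to 97.5. A list needed at least 3 detected members.

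The groups, lists, naming rule and most alternatives were fixed before the data were examined. The named genes were Casr, the 12 genes with the highest and the 12 with the lowest log2 ratio among those detected in both samples, the 3 largest bounds in each direction, and up to 3 members of each list with the largest absolute log2 ratio. For other cell types, sex-linked and housekeeping genes the 2 members with the strongest signals were added. Some members that this rule selects are not reported here. The lists covered calcium signalling, the vitamin D receptor pathway, basal, spinous, and granular and cornified envelope genes, barrier lipids, cholesterol synthesis, fatty acid synthesis, cell adhesion, proliferation, Wnt, hedgehog, hair follicle and hair keratins, stress keratins with antimicrobial proteins and cytokines, interferon response, epidermal transcription regulators, growth factor signalling, immediate early and heat shock genes, ER stress, antioxidant genes, circadian clock, housekeeping, sex-linked, ribosomal and respiratory chain genes. Marker lists covered fibroblasts, endothelium, melanocytes, skeletal muscle, erythroid cells and platelets, adipocytes, sebocytes, Langerhans and myeloid cells, T cells, mast cells, Schwann cells and nerve, Merkel cells and hair follicle keratinocytes. The ribosomal pattern also took in 4 Rps6k kinase genes.

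The procedure was tested on simulated data for this comparison of 8564 genes. Of 50 genes each with a planted 1.5-fold, 2-fold, 3-fold or 4-fold difference, 22%, 74%, 98% and 100% were called at least 1.5-fold apart. Of 8364 unchanged genes, 0% were. The simulated noise was the spread of log2 ratios between probes of a gene (SD 0.11). It held no variation between animals, pools or hybridisations, so the 0% followed from this setting and gives no false positive rate. The background in the signal lowered the median log2 ratio recovered for planted 2-fold genes to 0.76. Of 100 unchanged lists of 25 members 9 lay outside the central range, and of 100 lists shifted by 0.1 on the log2 scale 87 did.

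Alternatives comprised quantile normalization, background correction from detection p-values (neqc) and median scaling of the intensities before normalization, the series' value table, loess centring, an offset of 50 in place of the floor, other detection filters, the mean over a gene's probes, and 2-fold and 1.3-fold thresholds. List members were also restricted to those with strong signals and left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for quantile normalization and neqc.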

Results

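Transcript levels were measured in the epidermis of 5-day-old mice that lacked the calcium-sensing receptor (CaSR, gene symbol Casr) in keratinocytes and in the epidermis of littermate controls. The receptor senses extracellular calcium, and its gene was deleted with a Cre recombinase driven by the keratin 14 promoter, which is active in basal keratinocytes. RNA from 3 mice was combined for each genotype and hybridised to 1 Illumina bead array, so the comparison rested on 1 control sample and 1 knockout sample. There were no replicates, no value below carries a replicate error, and the number of arrays limits the precision of every comparison. Of 25697 probes, 10888 (42.4%) were detected above background in the control sample and 10802 (42.0%) in the knockout sample. These probes gave 8564 genes detected in at least 1 sample, of which 7934 were detected in both.

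The array carried 1 probe for Casr, listed under the older name Gprc2a. Its normalised signal was 122.9 in the control sample (detection p-value 0.891) and 148.2 in the knockout sample (detection p-value 0.0639). It was not above background in either sample, and no fold is given. Whether the probe lies in the deleted part of the gene is not given in the sources used here, so it provides no check of the genotype labels.

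The comparison of knockout with control asks which epidermal transcripts differ when keratinocytes lack CaSR. Most genes had similar signals in both samples. Among genes detected in both, 93.9% lay within 1.2-fold, the log2 ratios (knockout over control) had a median of 0.01 and an SD of 0.15 across genes, and the log2 signals correlated with a Pearson r of 0.995 across genes, which are not independent replicates. At least 1.5-fold higher signals in the knockout sample were found for 16 genes, and at least 1.5-fold lower signals for 20 genes. With background-corrected values from the same arrays the counts were 219 and 221. Background left in the signal draws ratios towards 1, and its removal also widens the spread of dim genes. As a scale of precision within these arrays, different probes of the same gene gave log2 ratios with a pooled SD of 0.11 over 1840 genes, and 2 such SDs correspond to 1.17-fold. These probes share the same pools and hybridisations, so this SD holds no variation between pools or hybridisations.

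The largest difference towards a higher signal in the knockout sample among genes detected in both was in Chil1, which encodes a chitinase-like glycoprotein, with a signal of 4260 in the knockout and 1176 in the control (3.62-fold). Wfdc12, a member of the whey acidic protein family of protease inhibitors, was 3.02-fold higher (722.9 and 239.5). Acoxl, an acyl-CoA oxidase-like gene, was 2.82-fold higher, and the tetraspanin gene Tspan8 was 2.11-fold higher. A pair of serine protease inhibitor genes with strong signals followed. Serpinb3a reached 3540 in the knockout and 1940 in the control (1.82-fold), and its second probe gave a log2 ratio of 0.65. Serpina3b reached 8627 and 4749 (1.82-fold). The gasdermin gene Gsdmc was 1.76-fold higher on its brightest probe, while its other probes gave log2 ratios of 0.15 and 0.60. Serpinb6d was 1.70-fold higher, Slurp1, a secreted Ly6-type protein of keratinocytes, was 1.60-fold higher, and the growth factor gene Igf2 was 1.59-fold higher (2828 and 1776). Rbm45 and Tmem87a were 1.60-fold and 1.59-fold higher.

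Among genes with lower signals in the knockout sample that were detected in both, the chemokine gene Xcl1 (lymphotactin) was 2.35-fold lower, with 206.1 in the knockout and 484.2 in the control. Agpat2, an acyltransferase of phosphatidic acid synthesis, was 2.14-fold lower (289.5 and 618.1). Arg1, the arginase gene, was 2.02-fold lower (329.3 and 664.1). The alpha-globin gene Hba-a1 was 1.85-fold lower, and the carboxylesterase gene Ces4a 1.84-fold lower. Trex2, a DNA exonuclease of keratinocytes, was 1.70-fold lower, and the surface antigen gene Psca 1.69-fold lower. The brightest of these genes were Tmem45b (3350 in the knockout and 5457 in the control, 1.63-fold lower) and Ide, the insulin-degrading enzyme (2399 and 3807, 1.59-fold lower). Rgcc, Bsdc1 and Pdzk1 were 1.61-fold, 1.58-fold and 1.57-fold lower.

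**Figure D1:**
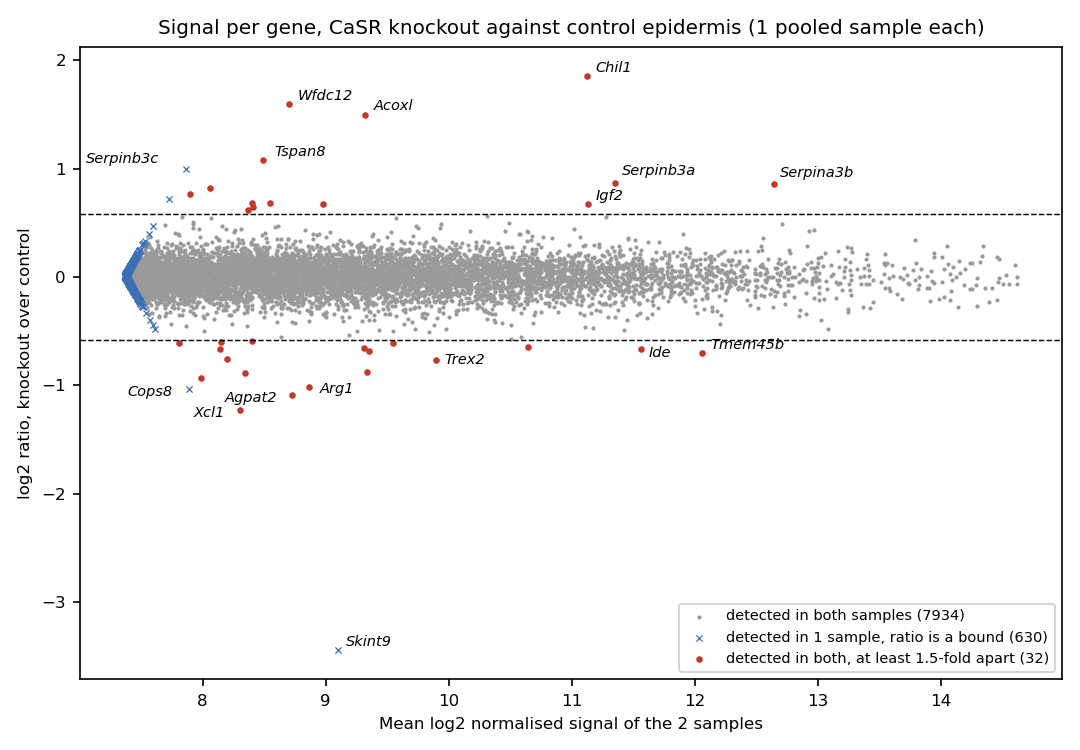
Log2 ratio of knockout over control against the mean log2 normalised signal of both samples, 1 point per gene, with dashed lines at 1.5-fold. Red points mark the 32 genes detected in both samples that were at least 1.5-fold apart, and blue crosses mark the 630 genes detected in 1 sample, for which the ratio is a bound.

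For 630 genes detected in 1 sample the ratio is a bound. Skint9, a butyrophilin-like gene of the family that includes the selecting element for epidermal gamma delta T cells, had a signal of 1810 in the control sample and 151.4, not above background, in the knockout sample, and was therefore at least 10.9-fold lower. Cops8, a subunit of the COP9 signalosome, was at least 2.05-fold lower, and Lrrc57 at least 1.40-fold lower. In the other direction Serpinb3c was at least 1.99-fold higher, Fetub, which encodes fetuin-B, at least 1.65-fold higher and Inka1 at least 1.38-fold higher in the knockout sample. Skint and Serpinb3 genes belong to families of near-identical copies, so their probes may also bind transcripts of relatives.

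Genes of the upper epidermis had lower signals in the knockout sample as a group. Of 37 detected members of the granular layer and cornified envelope list, 29 had a log2 ratio below 0, and the list median of -0.11 was lower than that of every one of 10000 random lists of the same size and expression. The differences were small in most members. Klk6, a kallikrein-related protease, was the member past 1.5-fold (1276 in the knockout and 2001 in the control, 1.57-fold lower). Ivl, which encodes the cornified envelope precursor involucrin, was 1.40-fold lower (2319 and 3250). The transglutaminase gene Tgm5 was also 1.40-fold lower on its brightest probe, with log2 ratios between -0.43 and -0.14 on its others. Loricrin and filaggrin-2, named after their values were seen, had log2 ratios of -0.03 (Lor) and -0.15 (Flg2).

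The layers below did not stand apart as groups. The spinous list had a median of -0.01 over 17 detected members (percentile 35.8), with Sbsn at -0.31, Krt77 at -0.19 and Krt10, a keratin of the spinous layer, at 0.22. The basal keratinocyte list had a median of 0.05 over 19 members (percentile 86.4), although the basal keratin genes Krt5 and Krt14 had log2 ratios of -0.28 and -0.20. Genes of cell adhesion and junctions had a median of 0.04 over 28 members (percentile 86.4). Ctnnb1, which encodes beta-catenin, was 1.28-fold higher (log2 ratio 0.20 on another probe), and Cldn4 was 1.17-fold lower.

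Genes of lipid synthesis also had lower signals in the knockout sample. Beside the granular and lipid lists, the marker list of hair follicle keratinocytes had a low median as well (-0.21), through its keratin genes. The sebocyte markers, which share members with the lipid lists, had a median of -0.13 with 3 of 7 members above 0, which turned to 0.041 with 1 member left out and lay inside the random range without the shared members. In the barrier lipid and ceramide list 25 of 33 detected members had a log2 ratio below 0, with a median of -0.13 that none of the 10000 random lists reached. Degs2, an enzyme of phytoceramide synthesis, was 1.36-fold lower, the ceramide synthase gene Cers4 was 1.37-fold lower on its brightest probe with -0.04 on another, and the phospholipase gene Pla2g2f was 1.24-fold lower. For cholesterol synthesis the median was -0.09 over 19 members, 15 of them below 0, at percentile 0.575. Msmo1, a sterol demethylation enzyme, had a log2 ratio of -0.30. For fatty acid synthesis the median was -0.08 over 19 members, 13 of them below 0, at percentile 1.42. Besides Agpat2 this list included Elovl6, a fatty acid elongase with a signal of 7374 in the knockout and 10285 in the control (1.39-fold lower), and Acss2 (1.34-fold lower, with 0.03 on another probe). Without the members shared with other lists that stood apart, the fatty acid median was -0.055 and lay inside the random range.

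In the hair follicle and hair keratin list 27 of 35 detected members had a log2 ratio below 0, with a median of -0.11 that none of the 10000 random lists reached. A split made after the values were seen showed that all 22 keratin and keratin-associated protein genes were below 0 (median -0.19), whereas 8 of the 13 other members were above 0 (median 0.11). Krt71, a keratin of the inner root sheath, was 1.32-fold lower (7253 and 9572), and the keratin-associated protein genes Krtap19-1 and Krtap14 were 1.31-fold and 1.29-fold lower. The shorter marker list of hair follicle keratinocytes had a median of -0.21 over 7 genes (percentile 0.05). All 7 are also in the hair list, so this is a part of that list and not a separate result. Its 5 keratin genes were below 0, including Krt31 at -0.32 and Krt27 at -0.21, and its 2 other members were above 0, the transcription factor gene Hoxc13 at 0.35 and Dsg4, named after its value was seen, at a bound of 0.17.

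**Figure D2:**
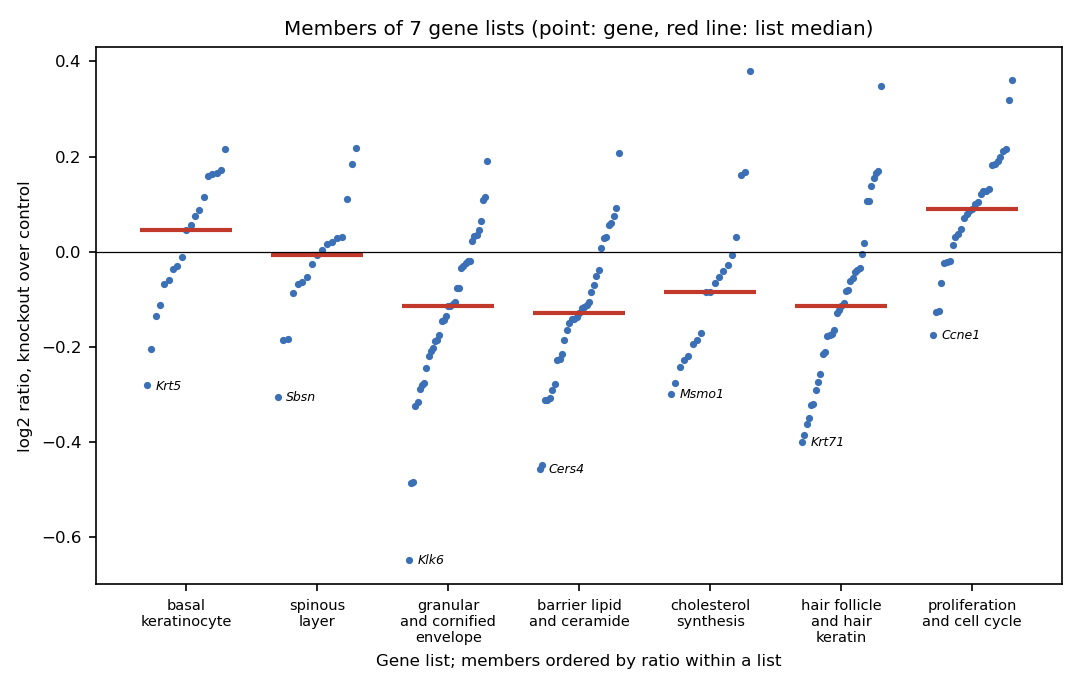
Log2 ratio of knockout over control for each detected member of 7 gene lists, 1 point per gene in order of its ratio, with a red line at the list median. The medians of the granular, barrier lipid, cholesterol and hair lists lie between -0.13 and -0.09, that of the spinous list at -0.01, and those of the basal and proliferation lists at 0.05 and 0.09.

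Proliferation genes had higher signals in the knockout sample as a group. Of 29 detected members 22 had a log2 ratio above 0, and the median of 0.09 lay at percentile 99.7 of the random lists. Mcm6, a subunit of the replicative helicase, was 1.29-fold higher with a log2 ratio of 0.23 on its other probe. Nusap1, a spindle protein, was 1.25-fold higher, and the mitotic cyclin gene Ccnb1 was 1.16-fold higher. No member reached 1.5-fold.

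Calcium signalling and vitamin D receptor genes, the pathways named in the series title, did not stand apart from random lists, nor did the other signalling lists. Genes of calcium entry, stores and signalling had a median of 0.02 over 25 detected members (percentile 60.5), with Plcb3 at 0.25, the calcium release channel gene Itpr1 at 0.21 and the store-operated channel gene Orai1 at -0.19. The vitamin D receptor pathway had a median of -0.01 over 15 members (percentile 29.9). Tlr2 was 1.47-fold higher, Ctsh 1.24-fold lower and Cyp27a1 at least 1.15-fold lower (up to 0.05 in log2 ratio on another probe), while the receptor gene Vdr itself, named after its value was seen, had a log2 ratio of -0.08. Wnt and beta-catenin genes had a median of -0.001 over 31 members (percentile 38.8), including Tcf7l2 at 0.25 and Tcf4 at 0.22. The 4 detected hedgehog genes had a median of 0.08 (percentile 87.8), with the ligand gene Shh at 0.38, Disp1 at 0.14 and Smo at -0.07 (up to 0.08 on another probe). Epidermal transcription regulators had a median of 0.02 over 30 members (percentile 63.5), with Cebpa at -0.29, Barx2 at -0.18 and Tfap2c at 0.29 on its brightest probe but between -0.25 and 0.19 on its others. Growth factor and PI3K signalling genes had a median of 0.02 over 24 members (percentile 68.1). In that list the EGF receptor ligand gene Btc was 1.47-fold lower and Bmp4 was 1.24-fold lower, opposite to Igf2.

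Stress and inflammation lists likewise lay inside the random range. The list of stress keratins, antimicrobial proteins and cytokines had a median of 0.00 over 25 members (percentile 41.5). Its largest members pointed in different directions. S100a9, a subunit of calprotectin, was 1.51-fold lower, while the protease inhibitor gene Stfa2 had a log2 ratio of 0.56. The prostaglandin E synthase gene Ptges had one of 0.44 (0.17 on another probe). Interferon response genes had a median of -0.03 over 15 members (percentile 12.4), with Isg15 at -0.17 and Ifi27l2a at -0.16. Immediate early and heat shock genes had a median of -0.02 over 22 members (percentile 22.7), with Fos at 0.49, Hspe1 at 0.47 and Hspb1 at -0.37. The median for ER stress and amino acid response was 0.01 over 20 members (percentile 55.0), with Hsp90b1 at 0.37. Asns was at 0.29 (0.13 on another probe) and Trib3 at -0.24 (between -0.06 and 0.00 on its other probes). For antioxidant and xenobiotic genes the median was -0.04 over 26 members (percentile 8.15), with Mt2 at 0.29, Gsta4 at -0.28 and Hmox1 at -0.27. For circadian clock genes it was -0.03 over 12 members (percentile 18.4). Per2 was at 0.26 (0.15 on another probe), Clock at -0.24 and Ciart at -0.24 (0.11 on another probe).

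Of the markers of other cell types, those of Langerhans and myeloid cells had higher medians in the knockout sample. Those of sebocytes, adipocytes and, as described above, hair follicle keratinocytes had lower ones. By the brightest probe of each gene, all 11 detected Langerhans and myeloid markers had a log2 ratio above 0, with a median of 0.12 (percentile 99.0), although 1 of them was below 0 after median scaling and after loess centring. H2-Aa had 0.23 and the bound for Adgre1 was 0.18. Csf1r had 0.18 on its brightest probe and -0.15 on the other. The bright class II genes H2-Ab1 and Cd74 had 0.12 and 0.03, while other probes reached down to -0.05 for H2-Ab1 and -0.06 for Cd74. Averaged over all probes of a gene, the myeloid median was 0.049 and lay inside the random range. Sebocyte markers had a median of -0.13 over 7 members (percentile 1.86), with Awat2, a wax synthase of sebaceous glands, at -0.50, Scd1 at -0.21, Mgst1 at 0.36 and Mc5r at 0.43, and leaving out 1 member with a low ratio turned this median to 0.041. The 6 detected adipocyte markers had a median of -0.10 (percentile 2.11), with Cfd at -0.36, Pparg at -0.34 (-0.03 on another probe) and Lpl at 0.14. Among genes detected in both samples the adipocyte median was -0.10 and lay inside the random range.

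Apart from these and the hair follicle markers, the marker lists with at least 3 detected members lay inside the random range. T cell markers had a median of -0.07 over 9 members (percentile 5.92), with Coro1a at 0.34 on its brightest probe but between -0.07 and -0.06 on its others, Laptm5 at 0.14, Nkg7 at -0.24, Cd3d at -0.17 and Cd3g at -0.07. Erythroid and platelet markers had a median of -0.08 over 5 members (percentile 5.88), and apart from Hba-a1 they included Slc4a1 at -0.08, a bound of -0.13 for Alas2 and a bound of 0.09 for Eraf. Fibroblast markers had a median of 0.03 over 12 members (percentile 73.4), with Vim at -0.22, Bgn at 0.18, Fbln2 at 0.14 and Fbln1 at 0.10. Melanocyte markers had a median of 0.0002 over 8 members (percentile 41.9), with Ednrb at 0.10, Mlana at -0.10, Tyrp1 at 0.06, Gpnmb at -0.03 and Dct at 0.03. Skeletal muscle markers had a median of 0.06 over 7 members (percentile 87.9), with Atp2a1 at 0.17, Myl1 at 0.09, a bound of 0.09 for Pvalb, and Tnni2 and Mylpf both at -0.02. Schwann cell and nerve markers had a median of -0.07 over 4 members (percentile 9.87), with Cnp at -0.21 (-0.01 on another probe), Mbp at -0.08 and a bound of -0.06 for Ngfr. Detected endothelial markers numbered 2 (Egfl7 at 0.04 and Ramp2 at 0.01), Krt8 at 0.02 was the 1 detected Merkel cell marker, and 0 mast cell markers were detected.

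The Y-linked genes Ddx3y and Eif2s3y were 1.34-fold and 1.28-fold higher in the knockout sample, and Xist, expressed from the inactive X chromosome, had a log2 ratio of -0.03 on its brightest probe and -0.25 on the other. Both samples contained all 3 transcripts. The list median of 0.36 (percentile 99.97) is the value of Eif2s3y alone and joins Y-linked genes with Xist, so it does not describe the list as a group. With a detection p-value limit of 0.05 it was 0.050 and without a detection filter 0.0087, both inside the random range. Housekeeping genes had a median of -0.02 over 14 members (percentile 30.2), with B2m at -0.33, Ppia at -0.27 and Rpl13a at 0.20. Actb was at -0.13 on its brightest probe and between -0.41 and -0.01 on its others. Ribosomal protein genes had a median of 0.01 over 66 members (percentile 62.6), with Rps25 at -0.33, Rpl5 at -0.25 and Rps27l at 0.24, and this median was -0.04 after median scaling of the arrays. Nuclear-encoded genes of the respiratory chain had a median of 0.02 over 72 members (percentile 81.5), or -0.007 after median scaling, with Cox6c at 0.55, Ndufb6 at 0.37 and a bound of 0.40 for Cox7b.

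**Figure D3:**
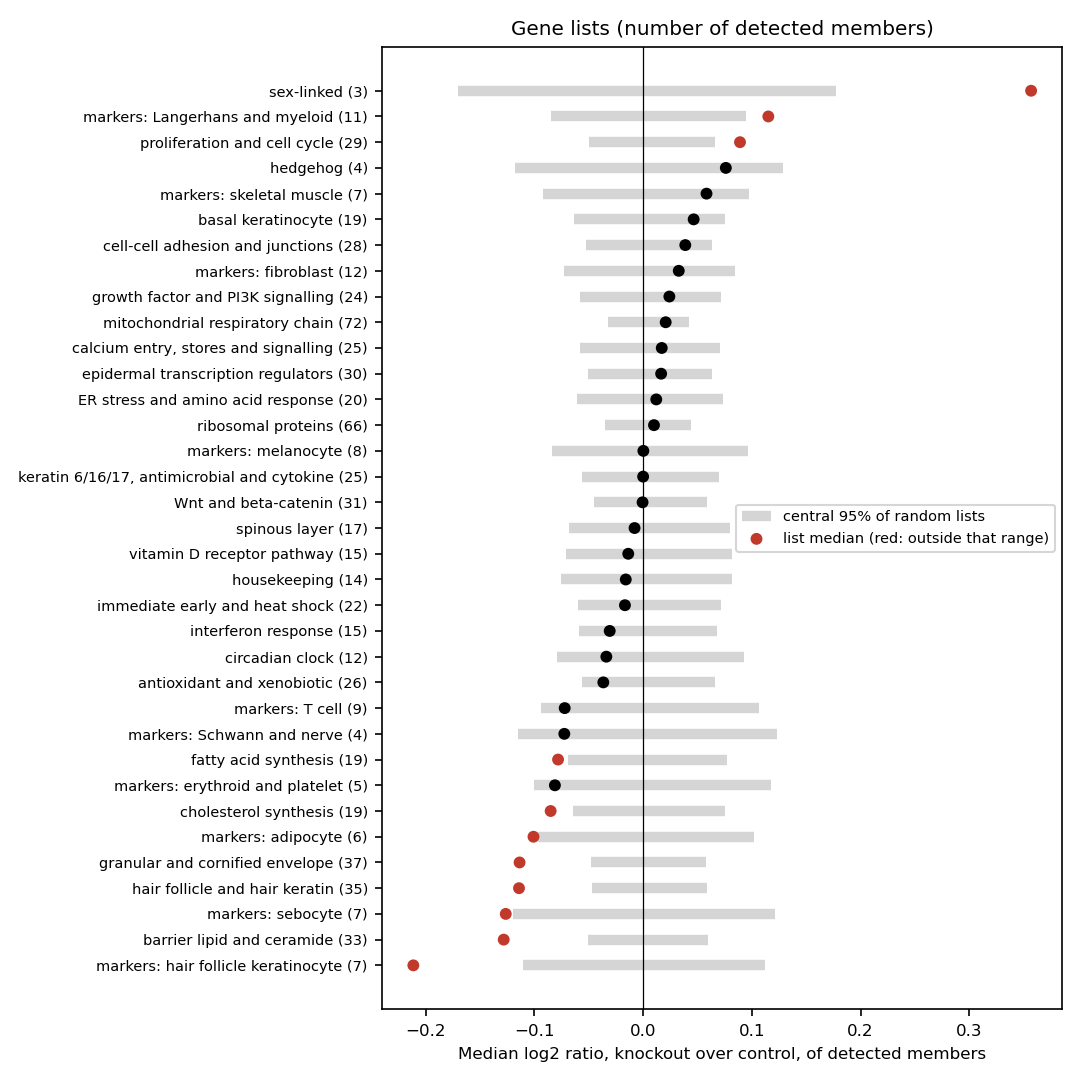
Median log2 ratio of knockout over control for 35 gene lists with at least 3 detected members (points), each with the central 95% of the medians of 10000 random lists of the same size and expression (grey bars). Red points mark the 11 lists outside that range, 8 below it and 3 above it.

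Of the 35 lists, 11 lay outside the central 95% of their random lists, 8 below and 3 above. On simulated data 9 of 100 unchanged lists lay outside that range. All detected hair follicle markers are also in the hair list, so these lists are not separate results. Other lists share members too and genes of a pathway vary together, so the percentiles describe this pair of samples and do not measure how pools of the same genotype vary.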

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

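Tests of lists without shared members, of the ribosomal list without kinases, and of strong-signal members of the granular, barrier lipid and hair lists were chosen after seeing the data. No paired analysis was possible because each group has 1 sample, and no array could be left out for the same reason. Of 30 named genes at least 1.5-fold apart, 27 stayed so under every setting that gave them a value, the exceptions being Bsdc1, S100a9 and Gsdmc. Some settings could hardly move a gene. The series' value table was identical to the main values, and a detection filter mainly decides which genes are kept. The genes were also chosen as extremes of these same arrays. Of the 11 lists that stood apart, 6 did so under every setting that could be run on them. Their medians ran from -0.15 to -0.06 for granular and cornified envelope, -0.15 to -0.12 for barrier lipids, -0.10 to -0.07 for cholesterol synthesis, -0.18 to -0.04 for hair, -0.22 to -0.08 for hair follicle markers and 0.04 to 0.12 for proliferation. Removal of shared members could not be run for the hair follicle markers, because all of them are in the hair list.

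Counts of genes higher and lower were 4 and 5 at 2-fold, 65 and 66 at 1.3-fold, and 219 and 221 at 1.5-fold after neqc, which removes background from the signal, widens the spread of dim genes and included all 16 and 20 genes. Without a detection filter, undetected members entered lists at or near the floor. The median then became the ratio of the floors, 0.0087, for fatty acid synthesis, adipocyte and sebocyte markers (reversed) and for sex-linked and myeloid genes. With a detection p-value limit of 0.05 the medians were 0.050 for sex-linked genes and -0.033 for sebocytes, both inside the random range because more dim members entered. Sebocyte markers also lay inside after median scaling (-0.13) and without shared members (-0.13), and leaving out 1 member with a low ratio gave 0.041. Adipocyte markers lay inside with an offset of 50 (-0.10), among genes detected in both samples (-0.10), with strong-signal members (-0.077), with 1 member left out (-0.10) and without shared members (-0.10). The myeloid median was 0.049 over all probes and 0.12 for strong-signal members, both inside. Fatty acid synthesis without shared members gave -0.055, inside. Erythroid and T cell markers moved outside with 1 member left out, at -0.11 and -0.10. Medians near 0 of the calcium, fibroblast, melanocyte, ribosomal, respiratory chain and stress keratin lists changed sign under another normalization. Where the construction of a setting does not show it, the cause was not tested. Signal over background limits all folds of dim genes, since 42.4% and 42.0% of probes were detected.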

Other observations

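All gene families in the next paragraph, and the tests of suprabasal cell share, of pool differences and of a probe mismatch, were chosen after the values were seen.

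Families of proteases and protease inhibitors were examined because single members differed most, so the medians are given with and without the member of largest ratio, as values only. The 7 detected kallikrein-related genes, 5 of them in the granular list already described, all had lower signals in the knockout sample, with a median log2 ratio of -0.12 without Klk6 and -0.14 with it. They included Klk8 at -0.28 and Klk10 at -0.25. Late cornified envelope genes, all 13 in the granular list, were lower in 11 members (median -0.11, and -0.09 without Lce1e), and 1 member changed sign under another normalization. The 6 detected Wfdc genes had a median of 0.16, and 0.08 without Wfdc12. Wfdc5 was at 0.26 and Wfdc21 at 0.24. The 4 detected Serpina3 genes had a median of 0.22, and 0.15 without Serpina3b, with 1 member changing sign under another normalization. The 13 clade B serpin genes had a median of 0.05 (0.02 without Serpinb3c and 0.0045 after median scaling, with 2 members changing sign under another normalization), with Serpinb3a and Serpinb3b at 0.87 and 0.50, Serpinb3c at least 1.99-fold higher, and Serpinb6e at -0.43. Genes with symbols that begin with Sprr, 5 of them in the granular list, had a median of -0.05 over 6 members, and 0.02 without Sprr4. Of these, 3 were below 0 and 3 above, and those below included Sprrl3 (-0.13), which is not in the granular list. In the S100 family S100a8 (-0.39) and S100a9 (-0.60), the partners of calprotectin, were lower and S100a10 (0.45) was higher. Families named by symbol contain similar sequences, so members are not independent measurements.

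Granular, barrier lipid and hair lists had lower medians in the knockout sample. Over 4 other normalizations of the same arrays the highest percentile of any of the 3 medians was 0.02. The random lists were matched on mean signal and shift with the list. This percentile could therefore hardly move, and it does not test normalization or a trend with brightness. Counts of members below 0 use no random lists. After loess centring, which removes such a trend, they stayed at 29 of 37 (granular), 25 of 33 (barrier lipid) and 27 of 35 (hair). After median scaling they were 30, 26 and 27. These counts argue against a trend with brightness as the whole source of the low medians. A smaller share of all suprabasal cells would lower spinous genes alike. The spinous median, however, was 0.106 above the granular median (bootstrap 95% interval over genes 0.02 to 0.20). As far as genes can be treated as independent, this argues against such a share as the whole source of the low granular median in these pools. Both medians had been seen before, and the interval does not measure variation between pools. The barrier lipid and hair lists were not compared in this way. A difference between pools of pups unrelated to genotype, such as sex ratio or developmental stage, cannot be told apart from the genotype, because there was 1 pool for each genotype. The Y-linked genes Ddx3y and Eif2s3y were 1.34-fold and 1.28-fold higher in the knockout sample, and Xist had -0.03 and -0.25 on its probes. A larger share of male RNA in the knockout pool would give these directions, and its bearing on the 3 lists was not tested. In the hair list the low median came from keratin and keratin-associated protein genes, and an effect of the genotype stays open and untested.

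All 7 detected stefin A genes are the nearest detected neighbours of Casr on one side, and their median log2 ratio was 0.17 (0.16 without Stfa2), led by Stfa2 (0.56) and Stfa3 (0.43), the closest, with Csta3 at -0.23. Sequence of a donor strain kept around the targeted locus would mark neighbours and not a pathway. Per the labels, however, both groups carry floxed Casr alleles. Such sequence is therefore expected in both pools and would not by itself give a difference between them. Of the 20 detected genes nearest to Casr, 16 had a log2 ratio above 0 (47.5% of all genes were below 0). Their median absolute log2 ratio of 0.12 lay at percentile 91.6 of 7873 such windows. Windows around named genes that were not targeted lay at 92.3 (Chil1), 86.7 (Cops8), 67.5 (Serpinb3a), 54.8 (Acoxl), 46.4 (Skint9) and 14.9 (Wfdc12). The Casr window held 2 genes past the smallest fold threshold used, Stfa2 and Stfa3. At least as many were found in 4.75% of windows, and the Serpinb3a window also held 2. The Casr percentile falls between the bounds set for and against donor sequence, and the values of Stfa2 and Stfa3 had been seen before the test. The shared floxed alleles argue against flanking donor sequence as the source, unless it differed between the pools, which was not measured. An effect of the genotype on stefin A genes and a difference between the pools of pups cannot be told apart with these arrays. Per the labels, Cre is named for the knockout sample only, so the genotype joins CaSR loss with Cre.

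Skint9 was the gene with the largest ratio, with 1810 in the control sample and a signal not above background in the knockout sample. A haplotype difference spread over its region would mark its neighbours, but the median absolute log2 ratio of the 20 nearest detected genes lay at percentile 46.4. A haplotype limited to the Skint genes could not be seen this way, since 3 Skint genes were detected and the median covers 20 genes. A mismatch under the probe may also give the Skint9 value and cannot be told apart from loss of the transcript, since the array carried 1 Skint9 probe. A variant limited to Skint9 or to the Skint genes, and an effect of the genotype (CaSR loss together with Cre) on the gene, stay open as well. The other detected members, Skint3 and Skint4, were near the floor in the control sample and not above background in the knockout sample, with bounds of -0.25 and -0.03.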
